A study of Blumeria hordei with 48 samples.

How the data were processed

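Messenger RNA (polyA) of leaves inoculated with the powdery mildew fungus was sequenced on an Illumina HiSeq2000 in 48 libraries, 3 biological replicates for each of 16 combinations of plant, isolate and time. The deposited table held raw read counts per fungal gene, as its header names them, for 6477 gene models in 48 columns, 1 per library, and all columns were matched to the labels (0 unmatched). The submitters' processing notes name TopHat 1.3.2 and bedtools 2.13.2. The genome build, annotation, strandedness of counting, handling of reads with several matches and removal of host reads are not given in the sources used here.

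Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr (5507 of 6477 in both designs), libraries were scaled by TMM, and quasi-likelihood F-tests (glmQLFit with robust estimation, glmQLFTest) were adjusted by Benjamini-Hochberg, with calls at adjusted p < 0.05. TMM factors ran from 0.814 to 0.888 at 12 hpi and from 1.01 to 1.13 at the other times. Comparisons of avirulent with virulent infections and of time steps used a fit of all 48 libraries with the 8 groups of virulence and time named for the model in the labels (40 residual degrees of freedom, common biological coefficient of variation 0.143). Effects of MLA1, of isolate and of their interaction used a fit with 16 groups (32 residual degrees of freedom, coefficient 0.0903), which pools the spread over groups of 3. Changes over time were tested jointly by an F-test over the 3 steps. Counts at an unadjusted p < 0.05 are given beside some results. Where no gene differs, a share of about 0.05 of the genes tested would lie there. CPM are TMM-scaled counts per 1000000; the prior count for log2 CPM was 2. The designs, tests, alternatives and rule for named genes were fixed before the data were examined, apart from those said to be added later.

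The rule for named genes took, per comparison, the 5 genes with the largest rise and the 5 with the largest fall among those called, with a mean log2 CPM of at least 3 and no overlap between the groups (for 9 libraries against 9, at least 8 beyond the median of the other group). As the table pairs no identifier with a name, at most 2 that rose and 2 that fell are printed for each comparison. A gene with 0 counts in a group is given as a bound against 3 counts over that group, and one with 1 to 3 counts as a ratio of summed counts over summed library totals, without TMM factors, with a 95% counting interval.

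Fungal totals per library were compared by exact permutation tests of log10 totals (220 splits of 3 against 9, smallest two-sided p 0.1 for 3 against 3). The 48 pairs of replicates were checked for duplication: chi-square per gene was 1.23 to 2.63, so none was a copy of another. Replicate numbers did not pair libraries across groups: deviations of libraries with the same number correlated by 0.000591 on average over genes, and 14 of 48 libraries correlated best with their own number. The pipeline was tested on simulated data with the real library totals. All libraries had 1 mean share per gene, with the spread of the fit of 16 groups. In each simulation 200 genes were changed, by 1.5-fold, 2-fold or 4-fold. With fewer changed genes the adjustment is stricter, so the recovered shares would be lower. For MLA1 under K1 at 24 hpi, 89.4% of 4-fold, 60.9% of 2-fold and 31.2% of 1.5-fold changes were recovered. For avirulent against virulent at 24 hpi, 66.7% of 2-fold changes were recovered. That figure may be too high, as the real fit of 8 groups had a larger coefficient of variation (0.143 against 0.0903).

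Alternatives were median-of-ratios (RLE) factors, DESeq2, no filter, a stricter filter (at least 1 CPM and 10 counts in 12 libraries), a replicate block, each library left out, fewer libraries in the fit, 16 groups in place of 8 and totals without the 10 most abundant genes. Added after the data were seen were library totals alone, omission of the libraries under 100000 counts, rows with identical counts taken once (bgh06532 and bghG008575000001001 shared all 1256 counts), thinning of counts, classes of genes by time of highest level, and differences of the MLA1 and isolate effects between times. Lists of fungal gene groups and a panel of effector names had been fixed beforehand, but identifiers without names gave 0 members for each, so tests of lists, of effector peak times, of scaling without candidate effectors and of the peak times of all such effectors were not run.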

Results

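RNA was sequenced from leaves of immunocompromised Arabidopsis thaliana (a pen2 pad4 sag101 triple mutant of the Columbia-0 accession) inoculated with the barley powdery mildew fungus, and reads on 6477 fungal gene models were counted. The plants did or did not express MLA1-HA, a barley immune receptor that recognises the fungal effector AVRA1. The fungal isolate was K1, which carries AVRA1, or A6, which carries other effectors. Leaves were taken at 6, 12, 18 and 24 hours post inoculation (hpi), with 3 biological replicates in each of the 16 groups, 48 libraries in all. The study's labels called K1 on plants with MLA1 avirulent (3 libraries per time) and the remaining 3 combinations virulent (9 libraries per time). The gene identifiers carried no names, products or positions, so genes are given by identifier alone.

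The total of fungal counts per library ranged from 67605 (K1 on plants with MLA1, 24 hpi, replicate 1) to 663971 (the same combination at 6 hpi, replicate 1), with a median of 271780. The median total was 393344 at 6 hpi, 305188 at 12 hpi, 230886 at 18 hpi and 206317 at 24 hpi. A total of 43 gene models had no count in any library and 5507 passed the filter on low counts. The 50 most abundant genes took 15.6% to 18.1% of the counts in the 12 hpi libraries and 11.5% to 14.4% in those of the other times. Time separated the libraries on the leading principal components, which held 42.5% and 22.2% of the variance. On the fifth component (2.22%) the library with the lowest total lay at -47.3, against 0.814 and 1.55 for the other 2 of its group. Intervals and limits at 0 counts given here cover counting error alone. A ratio with such an interval, like each limit, divides counts summed over the libraries of a group by their summed totals, so it can differ by over 1.5 times from the ratio of the mean CPM beside it, in which a shallow library weighs as much as a deep one.

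**Figure D1:**
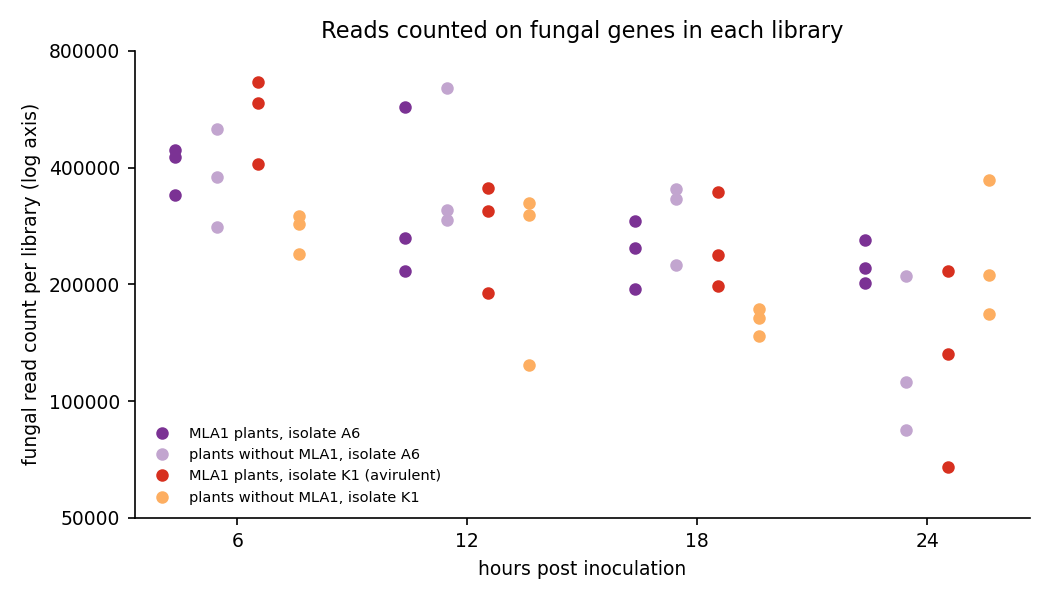
Total fungal counts of each of the 48 libraries (vertical axis, read counts, log scale) against hours post inoculation, 1 point per library, coloured by plant and isolate. The lowest total was 67605 and the highest 663971, both in K1 on plants with MLA1.

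The first question was how fungal transcripts changed over time in the infections labelled virulent. From 6 to 12 hpi in virulent infections, bgh02329 rose from 2.81 ± 4.22 to 4343 ± 318 CPM (normalised read counts per 1000000, mean ± SD, n = 9 at each time), a log2 fold change of 10.49 (SE 0.225, edgeR adjusted p = 3.57e-41). The gene bghG001226000001001 rose from 0.604 ± 1.21 to 686 ± 165 CPM. With 2 counts over the 9 libraries at 6 hpi, its ratio was 1253 (95% counting interval 346 to 10354.5). Over this step bgh01602 fell from 49.1 ± 10.9 to 4.07 ± 2.86 CPM (log2 -3.39) and bgh00349 from 388 ± 89.1 to 44.8 ± 19.6 CPM (log2 -3.17). From 12 to 18 hpi, bghG000359000001001 rose from 4.47 ± 3.16 to 195 ± 138 CPM (log2 5.48) and bgh06754 from 17.9 ± 8.23 to 622 ± 416 CPM (log2 5.15). The 9 libraries pool 3 combinations of plant and isolate, so these means and SDs also hold differences between isolates. At 18 hpi K1 on plants lacking MLA1 stood at 43.1 ± 15.6 and 174 ± 35.2 CPM for these 2 genes. That was below A6 on the same plants (log2 -2.92 and -2.62). In the same step bghG002249000002001 fell from 295 ± 43.6 to 13.4 ± 9.67 CPM (log2 -4.52) and bghG004376000001001 from 94.8 ± 26.2 to 5.61 ± 5.68 CPM (log2 -3.93). From 18 to 24 hpi, bgh05102 rose from 2.49 ± 3.64 to 121 ± 31.4 CPM (log2 5.48) and bgh06298 from 59.2 ± 11.8 to 370 ± 66.3 CPM (log2 2.62). The largest falls of that step were in bghG005334000001001, from 210 ± 50.3 to 19.7 ± 11.2 CPM (log2 -3.51), and bghG005335000001001, from 236 ± 72.3 to 22.8 ± 17.9 CPM (log2 -3.32).

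Of 5507 genes tested, 4519 (82.1%) changed over time in virulent infections. The step from 6 to 12 hpi had 1841 genes higher and 2035 lower at adjusted p < 0.05, of which 1131 and 687 moved by over 2-fold. The following steps had 1266 higher and 1282 lower, then 481 higher and 615 lower. Among the changed genes, 1708 had their highest group mean at 6 hpi, 1348 at 12 hpi, 500 at 18 hpi and 963 at 24 hpi. Counted over the 2334 genes with at least a 2-fold range, 729, 916, 235 and 454 were highest at these times. Changes into and out of 12 hpi depended on the scaling. In the step to 12 hpi RLE (median-of-ratios) factors gave 1978 higher and 1814 lower and DESeq2 1985 and 1799, and in the step to 18 hpi 1124 and 1389, and 1095 and 1376. With library totals alone, a setting added after the data were seen, the step to 12 hpi had 1393 genes higher and 2886 lower and the step to 18 hpi 2432 higher and 828 lower. The median of all genes was then -0.43 in place of -0.07 and 0.34 in place of 0.07 (log2).

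The second question was whether the same steps occurred in avirulent infections, K1 on plants with MLA1 (n = 3 at each time). From 6 to 12 hpi, bgh02329 went from 0 counts in the 3 libraries to 4343 ± 142 CPM, at least 2642-fold higher against a limit of 3 counts over the group. The gene bgh04352 rose from 0.893 ± 1.55 CPM (2 counts) to 842 ± 86.8 CPM, a ratio of 756 (209 to 6260.2). In contrast, bghG006402000002001 fell from 112 ± 12.5 to 8.58 ± 4.49 CPM (log2 -3.73, edgeR adjusted p = 1.77e-10). From 12 to 18 hpi, bgh04920 rose from 3 counts (3.35 ± 3.20 CPM) to 325 ± 69.7 CPM, a ratio of 81.4 (27.5 to 397), and bgh02701 from 0 counts to 28.9 ± 14.4 CPM, at least 6.84-fold. Both bghG004376000001001 and bghG007401000001001 fell to 1 count, from 105 ± 4.42 and 55.6 ± 6.36 CPM, ratios of 84.8 (14.8 to 3389.5) and 45.1 (7.66 to 1821.6). From 18 to 24 hpi, bgh05102 rose from 0 counts to 50.6 ± 6.33 CPM, at least 13.2-fold, and bgh04856 from 8.85 ± 0.901 to 92.2 ± 23.8 CPM (log2 3.37). The gene bgh02824 fell from 19.3 ± 15.1 CPM to 0 counts, at least 2.65-fold, and bghG003457000001001 from 38.3 ± 21.1 CPM to 1 count (4.75 ± 8.22 CPM), a ratio of 16.4 (2.74 to 669).

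The avirulent steps had 1403 genes higher and 1295 lower from 6 to 12 hpi, 476 and 727 from 12 to 18 hpi, and 136 and 281 from 18 to 24 hpi, each tested with 3 libraries against 3. With library totals alone the first step had 1086 higher and 2162 lower (median of all genes -0.40 in place of -0.06) and the next 1002 higher and 515 lower (0.26 in place of 0.03). The fall of bgh00191 from 6 to 12 hpi, from 7.12 ± 3.62 CPM to 0 counts (at least 1.62-fold, adjusted p = 0.0497), was lost at adjusted p from 0.0550 to 0.146 with median-of-ratios scaling, without the filter, with a replicate block, without the 2 libraries under 100000 counts, and without avirulent replicates 2 or 3 at 6 hpi or 1, 2 or 3 at 12 hpi. Without avirulent replicate 2 at 24 hpi, the last step had 75 genes higher and 141 lower, and bgh02824 (adjusted p = 0.133) and bghG003457000001001 (adjusted p = 0.135) lost their calls, as bgh02824 did without replicate 1 at 18 hpi (adjusted p = 0.109).

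Tested directly, the avirulent step differed from the virulent one in 0 genes from 6 to 12 hpi (edgeR, 388 at an unadjusted p < 0.05, DESeq2 4) and in 0 genes from 12 to 18 hpi (edgeR, 391 unadjusted, DESeq2 1). From 18 to 24 hpi it was higher in 6 genes and lower in 21 (DESeq2 16 and 37). The counts of 0 became 3 without replicate 2 and 5 without replicate 3 of K1 on plants lacking MLA1 at 6 hpi, and 1 without replicate 3 of A6 on plants with MLA1 or of K1 on plants lacking it at 18 hpi. The 27 genes of the last step became 3 without avirulent replicate 2 at 24 hpi, and 9, 7 and 15 without avirulent replicates 1, 2 and 3 at 18 hpi. They became 17 without replicate 2 of A6 on plants with MLA1 at 24 hpi, and 16 without replicate 3 of A6 on plants lacking MLA1 at 18 hpi.

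**Figure D2:**
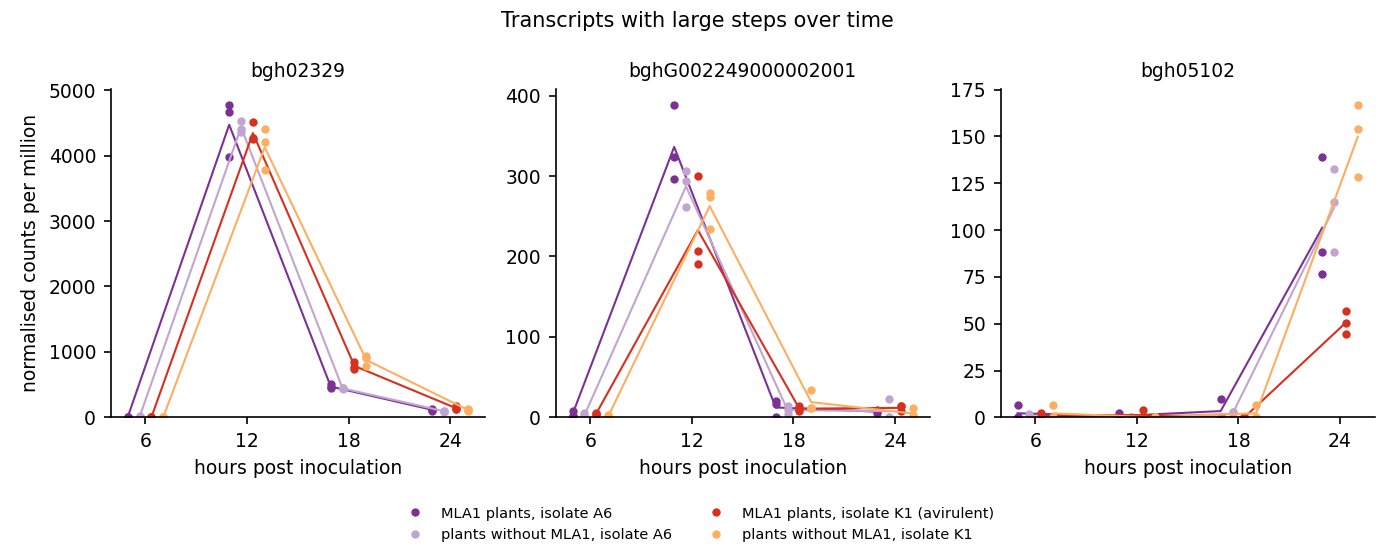
CPM of 3 genes (bgh02329, bghG002249000002001 and bgh05102) against hours post inoculation, with points for libraries and lines for the means of 3 libraries in each plant and isolate combination. In virulent infections bgh02329 averaged 4343 CPM at 12 hpi, bghG002249000002001 295 CPM at 12 hpi and bgh05102 121 CPM at 24 hpi.

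The third question was which fungal transcripts differed between avirulent and virulent infections, the grouping named for the model in the labels. At 24 hpi, bgh04165 stood at 81.7 ± 41.0 CPM in avirulent (n = 3) and 21.9 ± 14.8 CPM in virulent libraries (n = 9), a log2 difference of 1.51 (SE 0.479, edgeR adjusted p = 0.0413), and bgh01731 at 187 ± 67.8 against 71.2 ± 26.5 CPM (log2 1.43, adjusted p = 0.00161). In the other direction, bgh02824 had 0 counts in avirulent libraries and 12.5 ± 7.19 CPM in virulent ones, at least 1.72-fold lower (adjusted p = 0.0417). The gene bgh02925 had 3 counts (9.67 ± 8.38 CPM) against 182 ± 109 CPM, a ratio of 22.1 (7.47 to 108, adjusted p = 0.0346). In K1 on plants lacking MLA1, bgh02925 stood at 58.1 ± 28.1 CPM at that time. In all, 109 genes were higher and 231 lower in avirulent libraries at 24 hpi, and 17 and 100 of them had fitted differences over 2-fold. Without the 2 libraries under 100000 counts, avirulent replicate 1 and replicate 1 of A6 on plants lacking MLA1, 58 were higher and 172 lower.

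At 6 hpi the avirulent libraries were higher than the virulent in 77 genes and lower in 20. Among them, bgh04130 was at 21.9 ± 3.08 against 6.44 ± 5.57 CPM (log2 1.74, SE 0.440, edgeR adjusted p = 0.0240) and bghG005862000001001 at 164 ± 21.1 against 61.5 ± 37.6 CPM (log2 1.48). The genes bgh02918, at 16.6 ± 1.60 against 54.2 ± 25.2 CPM (log2 -1.77), and bgh00896, at 34.6 ± 3.28 against 67.3 ± 13.8 CPM (log2 -0.99), were lower. At 12 hpi 5 genes were higher and 4 lower. Of these, bgh04743 was at 203 ± 50.5 against 102 ± 36.6 CPM (log2 1.02) and bghG005703000001001 at 354 ± 35.8 against 220 ± 33.7 CPM (log2 0.67), with bgh02918 at 61.0 ± 15.6 against 186 ± 61.4 CPM (log2 -1.68) and bgh01933 at 29.3 ± 10.1 against 91.3 ± 22.0 CPM (log2 -1.61). At 18 hpi 23 genes were higher and 20 lower. They included bgh00420, at 222 ± 26.5 against 82.0 ± 35.5 CPM (log2 1.51, adjusted p = 7.96e-06), bgh00947, at 309 ± 71.7 against 154 ± 39.4 CPM (log2 0.99), bgh05491, at 13.9 ± 7.33 against 49.9 ± 17.3 CPM (log2 -2.02), and bgh02130, at 25.6 ± 3.58 against 71.2 ± 24.97 CPM (log2 -1.44).

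All avirulent libraries were of isolate K1 and 6 of every 9 virulent ones of A6, so this grouping also compared isolates. On plants lacking MLA1, bgh02918 was lower in K1 than in A6 at 6 hpi (log2 -1.77) and at 12 hpi (log2 -1.05). With each plant and isolate combination as its own group, the counts were 291 higher and 139 lower at 6 hpi, 200 and 110 at 12 hpi, 201 and 135 at 18 hpi, and 277 higher among 578 at 24 hpi. DESeq2 gave 77 higher and 39 lower at 6 hpi, 16 and 17 at 12 hpi, and 34 and 35 at 18 hpi; library totals alone gave 6 and 2 at 12 hpi. A fit of the 12 libraries of 1 time gave 0 genes in edgeR at 6 hpi (781 at an unadjusted p < 0.05 in the fit of 48, DESeq2 116) and 3 at 12 hpi.

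Many of these calls depended on single libraries, and at 6, 12 and 18 hpi the direction followed the combination left out. Leaving out any avirulent library lowered the count, and leaving out any of K1 on plants lacking MLA1 raised it. At 6 hpi leaving out any A6 library lowered it. The 97 genes at 6 hpi became 25, 0 and 11 without avirulent replicates 1, 2 and 3, and 189, 203 and 251 without replicates 1, 2 and 3 of K1 on plants lacking MLA1. They became 38, 42 and 41 without those of A6 on plants with MLA1, and 46, 41 and 52 without those of A6 on plants lacking it. The 9 genes at 12 hpi became 0, 0 and 3 without the avirulent replicates in the same order, 27, 108 and 91 without those of K1 on plants lacking MLA1, 4 without replicate 1 or 3 of A6 on plants with MLA1, and 5 without replicate 1 of A6 on plants lacking it. The 43 genes at 18 hpi became 2, 5 and 7 without the avirulent replicates, 93, 76 and 68 without K1 on plants lacking MLA1, and 17, 13 and 25 without A6 on those plants. At 24 hpi the 340 became 255 (71 higher, 184 lower), 123 (26 and 97) and 215 (50 and 165) without avirulent replicates 1, 2 and 3.

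Every gene named above from 6, 12 and 18 hpi except bgh00420 lost its call without at least 1 avirulent replicate: at 6 hpi at adjusted p from 0.0539 to 0.154 (replicate 1, 2 or 3), at 12 hpi from 0.0727 to 0.286 (replicate 1, 2 or 3), and at 18 hpi from 0.0607 to 0.239 (replicate 1, 2 or 3). The call of bghG005703000001001 was also lost without A6 on plants with MLA1 replicate 1 (adjusted p = 0.0526) or 3 (0.0788), or on plants lacking it replicate 1 (0.0808), and that of bgh05491 without A6 on plants lacking MLA1 replicate 1 (0.0550) or 2 (0.0505). At 24 hpi, bgh04165, bgh02824 and bgh02925 lost their calls without each of the 3 avirulent replicates in turn (adjusted p from 0.0679 to 0.294), and bgh01731 without replicate 2 (adjusted p = 0.165). Without A6 on plants with MLA1 replicate 2, bgh04165 (adjusted p = 0.0775), bgh02824 (0.0874) and bgh02925 (0.0501) missed the threshold, and bgh04165 did so too without replicate 1 of that group (0.0576) or of K1 on plants lacking MLA1 (0.0579). Omitting A6 on plants lacking MLA1 replicate 1 left bgh04165 at adjusted p = 0.0542 and bgh02824 at 0.0505, and omitting its replicate 2 left bgh04165 at 0.0505. DESeq2 gave bgh02824 an adjusted p of 0.131.

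The fourth question was what MLA1 changed in a single isolate, K1, which carries the effector it recognises (3 libraries with MLA1 against 3 without at each time). At 24 hpi, bgh03378 stood at 131 ± 21.4 CPM with MLA1 and 46.2 ± 5.58 CPM without it (log2 1.53, SE 0.330, edgeR adjusted p = 0.000619), and bgh03544 at 75.9 ± 5.99 against 33.0 ± 16.8 CPM (log2 1.35, adjusted p = 0.0406). The gene bgh01006 had 2 counts with MLA1 (7.21 ± 7.12 CPM) against 69.4 ± 41.1 CPM, a ratio of 15.1 (3.99 to 128, adjusted p = 7.63e-05). Likewise, bghG006513000001001 had 1 count (1.53 ± 2.65 CPM) against 39.0 ± 18.2 CPM, a ratio of 14.3 (2.35 to 586, adjusted p = 0.0129). Among the genes tested at 24 hpi, 133 were higher with MLA1 and 254 lower, and 13 and 108 of them had fitted differences over 2-fold. DESeq2 gave 154 higher and 195 lower.

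At 18 hpi, 19 genes were higher with MLA1 and 14 lower. They included bgh03763, at 124 ± 56.1 against 44.3 ± 3.84 CPM (log2 1.41, edgeR adjusted p = 0.0367), bgh00420, at 222 ± 26.5 against 93.5 ± 46.8 CPM (log2 1.29), bgh02130, at 25.6 ± 3.58 against 79.8 ± 39.9 CPM (log2 -1.64), and bgh03293, at 29.8 ± 8.94 against 86.0 ± 24.9 CPM (log2 -1.44). With all libraries in the fit, bgh02918 was lower with MLA1 at 18 hpi (log2 -0.89, adjusted p = 0.0336) and at 24 hpi (log2 -1.99, adjusted p = 6.10e-10). Of the 33 genes called at 18 hpi, 24 had the same direction at 24 hpi, as had 56.6% of all genes, and 10 were also called there, against 1.10 if the calls were independent. At 6 hpi edgeR called 0 genes (289 at an unadjusted p < 0.05, DESeq2 0) and at 12 hpi 0 (273 unadjusted, DESeq2 0). Where no gene differs, a share of about 0.05 of the 5507 genes tested would lie under that unadjusted p. In simulated counts with the library totals of 6 hpi, 200 genes were changed. Of those changed 2-fold 83.6% and of those changed 1.5-fold 38.8% were recovered, shares that would be lower with fewer changed genes. Many differences of 1.5-fold or less at 6 hpi would therefore not be detectable with these libraries.

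Without replicate 2 of the plants with MLA1 at 24 hpi, 54 genes were higher and 115 lower, and without replicates 2 and 3 of those lacking it 76 and 208, and 85 and 192. The 33 genes at 18 hpi became 3 and 1 without replicates 2 and 3 of the plants with MLA1 and 6, 2 and 1 without replicates 1, 2 and 3 of those lacking it; DESeq2 gave 76 and a fit of these 6 libraries 92. The calls of bgh03763, bgh00420, bgh02130 and bgh03293 were each lost in at least 4 of the 6 omissions, at adjusted p from 0.0527 to 0.282. At 24 hpi, bgh03544 lost its call without replicate 1 (adjusted p = 0.0538), 2 (0.242) or 3 (0.0805) of the plants with MLA1 and without replicate 2 (0.240) or 3 (0.128) of those lacking it, and bghG006513000001001 without replicate 2 (0.0669) or 3 (0.0736) of the plants with MLA1.

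The fifth question, a control for the plant line, was whether MLA1 changed transcripts of A6, whose effectors it does not recognise. Over the mean of the 4 times (12 libraries against 12), bgh01822 was lower with MLA1, at 133 ± 36.1 against 190 ± 48.5 CPM (log2 -0.52, SE 0.104, adjusted p = 0.0132), and no other gene was called. At 6 hpi, bgh02560 (538 ± 26.7 against 355 ± 65.6 CPM, log2 0.58) and bgh03095 (726 ± 22.6 against 472 ± 123 CPM, log2 0.60) were higher. The gene bghG004158000001001 was lower at 18 hpi (52.9 ± 9.20 against 139 ± 10.9 CPM, log2 -1.38) and bghG001077000001001 at 24 hpi (54.4 ± 14.98 against 165 ± 43.2 CPM, log2 -1.46). These 5 genes were named after their values were seen, because so few were called. At 12 hpi edgeR called 0 genes (205 at an unadjusted p < 0.05, DESeq2 0). For the mean of the 4 times DESeq2 called 0 genes (edgeR 366 unadjusted), and simulated data with these totals recovered 98.5% of 2-fold and 73.4% of 1.5-fold changes. In that simulation 200 genes were changed, each at all 4 times. A change in few genes or at 1 time would be recovered less often. With a replicate block 1 of the 2 genes at 6 hpi was called, as with DESeq2, and 2 genes at 18 hpi. Without the filter 5 were called at 6 hpi. Omission of the 2 libraries under 100000 counts gave 2 at 18 hpi and 0 at 24 hpi (edgeR, 306 unadjusted, DESeq2 1 with all libraries).

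The single call over the mean became 0 without replicate 2 at 6 hpi, 1 at 18 hpi, 1 at 12 hpi or 3 at 24 hpi of the plants with MLA1, and without replicate 1 or 3 at 6 hpi, 2 at 12 hpi or 1 at 24 hpi of those lacking it. It became 2 without replicate 3 at 18 hpi of either plant or replicate 2 at 24 hpi of plants lacking MLA1, 4 without replicate 2 at 24 hpi of plants with MLA1, and 5 without replicate 3 at 24 hpi of plants lacking it. At 6 hpi the 2 calls became 41 (40 higher) without replicate 1 of plants lacking MLA1 and 0 without replicate 3 of those plants or replicate 1 or 3 of plants with MLA1. The 0 at 12 hpi became 1 without replicate 3 of plants lacking MLA1. The single call at 18 hpi became 0 without replicate 3 of plants with MLA1 or replicate 2 of those lacking it, and 2 without replicate 1 of plants with MLA1. That at 24 hpi became 0 without replicate 1 or 3 of plants with MLA1 or replicate 1 or 2 of those lacking it.

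The sixth question was whether the effect of MLA1 differed between the isolates, tested as the MLA1 effect under K1 minus that under A6 with 3 libraries in each of 4 groups per time. At 24 hpi, bgh01006 was lower by that difference (log2 -4.67, SE 0.979, edgeR adjusted p = 0.00439), as was bgh05314 (log2 -3.75, SE 0.862, adjusted p = 0.00906). Both fitted values rested on few reads in K1 with MLA1, 2 counts for bgh01006 and 3 for bgh05314, so their sizes were poorly determined. Under K1, bgh05314 stood at 6.45 ± 7.55 CPM with MLA1 and 65.0 ± 13.7 CPM without it, and under A6 at 53.5 ± 9.27 and 29.9 ± 19.2 CPM. The difference was positive for bgh01590 (log2 0.98, adjusted p = 0.00819) and bgh01153 (log2 0.93, adjusted p = 0.01001). In all 3 genes were higher and 47 lower at 24 hpi, and DESeq2 gave 14 and 39. The gene bgh02918 was among those lower at 24 hpi (log2 -1.43, adjusted p = 0.00466).

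At 18 hpi 11 genes were called and all were higher, with log2 differences from 0.96 to 2.06, though library totals alone, the stricter filter and omission of the 2 libraries under 100000 counts each gave 13 higher and 1 lower, and DESeq2 14 and 1. The 2 largest were bghG000359000001001 (log2 2.06, SE 0.461, edgeR adjusted p = 0.0339) and bghG000359000002001 (log2 2.00, SE 0.474, adjusted p = 0.0427). For bgh06754, 1 of the 11, the means at 18 hpi were 288 ± 59.98 CPM with MLA1 and 174 ± 35.2 CPM without it under K1, and 617 ± 164 and 1075 ± 233 CPM under A6. In edgeR 0 genes were called at 6 hpi (294 at an unadjusted p < 0.05, DESeq2 0) and 0 at 12 hpi (256 unadjusted, DESeq2 0). In simulated counts at the depth of 24 hpi this test recovered 27.7% of 2-fold and 75% of 4-fold differences.

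Omitting replicate 2 of K1 on plants with MLA1 at 24 hpi gave 2 genes in place of 50 and ended the calls of bgh01590 and bgh01153 (adjusted p = 0.0859 each), bgh01006 (0.0929) and bgh05314 (0.140). The 50 became 27 without replicate 2 of A6 on plants with MLA1, and 27 without replicate 3 of A6 on plants lacking it, where bgh01590 (0.0914) and bgh01153 (0.131) also missed the threshold. The 11 genes at 18 hpi became 1, 17 and 0 without replicates 1, 2 and 3 of A6 on plants with MLA1, and 0 without replicate 2 or 3 of K1 on these plants. They became 0 without replicate 3 of A6 on plants lacking MLA1, and 0 without replicate 1 or 2 of K1 on those plants (edgeR, 411 at an unadjusted p < 0.05 with all libraries, DESeq2 15). The calls of both named genes of 18 hpi were lost in each of these omissions except that of replicate 2 of A6 on plants with MLA1 (adjusted p from 0.0727 to 0.351), and that of bghG000359000002001 also without replicate 2 of A6 (0.0948) or 3 of K1 (0.173) on plants lacking MLA1. The 0 at 6 hpi became 19 and 2 without replicates 1 and 2 of A6 on plants lacking MLA1.

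The last gene comparison asked how the isolates differed on plants lacking MLA1, where the labels called both virulent. Over the mean of the 4 times (12 libraries against 12), bgh02574 stood at 186 ± 71.2 CPM in K1 and had 0 counts in A6, at least 223-fold higher in K1. The means of bgh04330 were 178 ± 97.6 against 11.1 ± 7.19 CPM in A6 (log2 3.98, SE 0.203, adjusted p = 3.47e-33). The gene bghG004177000002001 had 0 counts in K1 and 142 ± 51.3 CPM in A6, at least 127-fold lower in K1. For bgh03042 there was 1 count in K1 against 43.3 ± 28.3 CPM, a ratio of 117 (20.7 to 4653.3). In all 441 genes were higher in K1 and 370 lower. Single times gave 264 higher and 189 lower at 6 hpi, 195 and 214 at 12 hpi, 251 and 236 at 18 hpi, and 76 and 80 at 24 hpi. With library totals alone the split at 12 hpi was 258 and 148. Without replicate 1 or 3 of K1 at 6 hpi the split was 258 and 114 or 198 and 121, without replicate 1 of A6 at 12 hpi 143 and 139, and without replicate 3 of A6 at 24 hpi 56 and 53. Without replicate 2 or 3 of K1 at 12 hpi its 409 genes became 268 or 256, and without replicate 2 of K1 at 24 hpi the 156 became 102.

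Over all 24 libraries of each isolate, 2 genes had at least 100 counts in K1 and at most 3 in A6. They were bgh02574 (1230 against 1) and bgh01641 (178 against 2). The reverse held for 3 genes, bghG004177000002001 (988 against 2), bgh03042 (307 against 3) and bghG002102000001001 (132 against 3). This list of 5 was made after the data were seen.

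**Figure D3:**
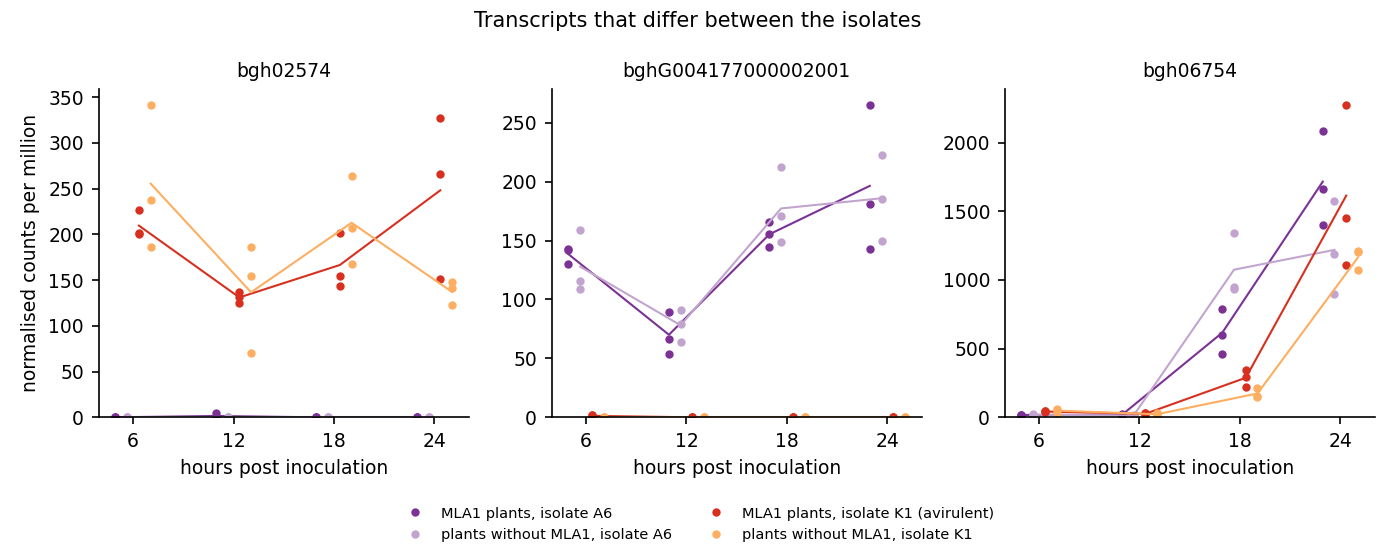
CPM of 3 genes (bgh02574, bghG004177000002001 and bgh06754) against hours post inoculation, with points for libraries and lines for the means of 3 libraries in each plant and isolate combination. Counts of bgh02574 came from K1 and those of bghG004177000002001 from A6 but for 1 and 2 counts, and bgh06754 at 18 hpi averaged 174 and 288 CPM in the K1 groups and 617 and 1075 CPM in the A6 groups.

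Totals of fungal counts were compared between avirulent and other libraries at each time by exact two-sided permutation tests of the log10 totals. Against the 9 virulent libraries the ratio of geometric means was 1.57 at 6 hpi (exact p = 0.0318, adjusted over 12 comparisons 0.382), 0.8995 at 12 hpi (exact p = 0.723), 1.12 at 18 hpi (exact p = 0.595) and 0.661 at 24 hpi (exact p = 0.214). Against A6 on plants with MLA1 the ratios were 1.36, 0.859, 1.05 and 0.551, and against K1 on plants lacking MLA1 1.98, 1.20, 1.58 and 0.528, at exact p of 0.1 or more, the smallest that 3 libraries against 3 allow. At 12 hpi the ratio to virulent libraries became 1.08 without avirulent replicate 3, that to A6 with MLA1 1.03 without the same library and 1.15 without A6 replicate 1, and that to K1 lacking MLA1 0.879 without K1 replicate 1. At 18 hpi the ratios to virulent libraries and to A6 with MLA1 became 0.961 and 0.901 without avirulent replicate 2, and the latter 0.945 without A6 replicate 3. The total in a library of infected leaves depends on both the amount of fungus and the sequencing depth, which these counts alone do not separate.

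**Figure D4:**
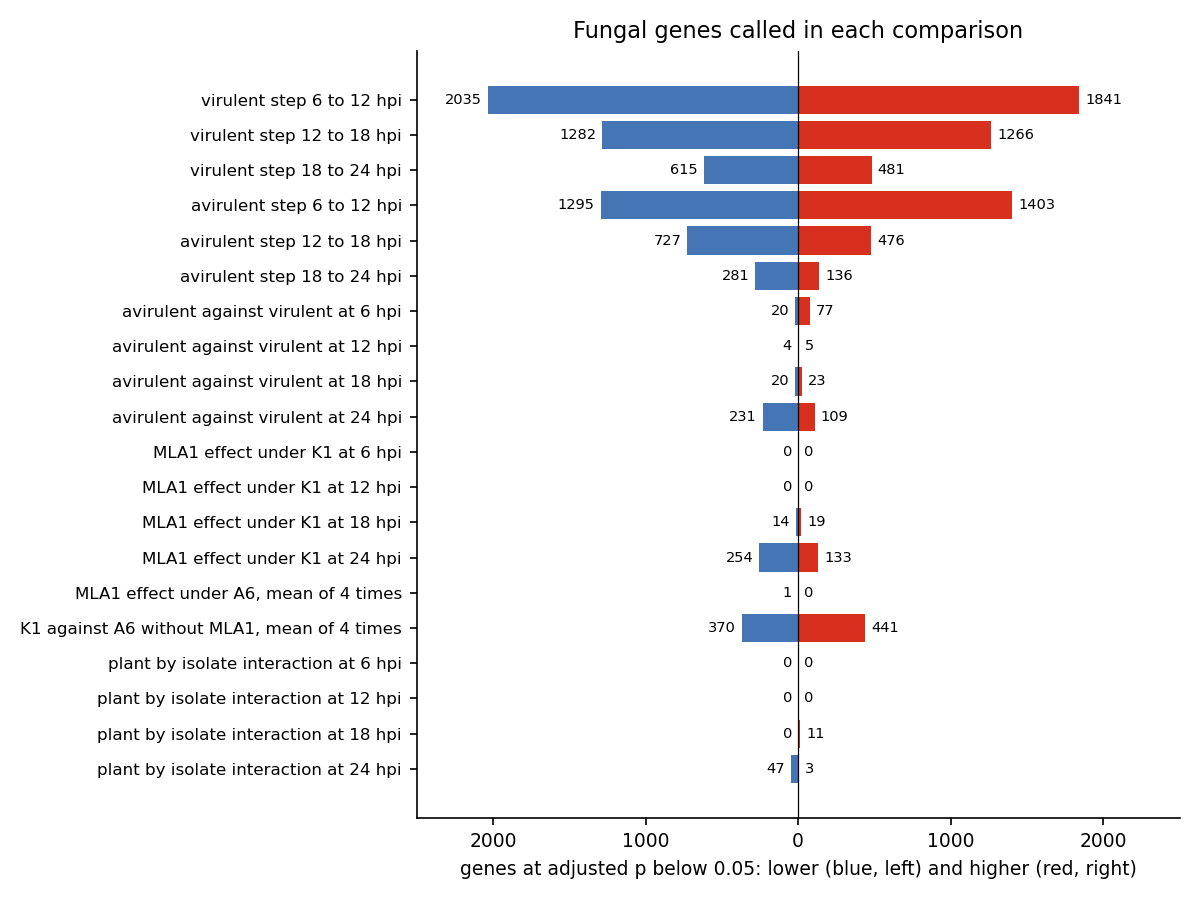
Numbers of genes called lower and higher at adjusted p < 0.05 in 20 comparisons, as horizontal bars to the left and right of 0. The bars range from 0 genes, as for MLA1 under K1 at 6 hpi, to 1841 higher and 2035 lower for the virulent step from 6 to 12 hpi.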

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

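The tests chosen only after the result was seen were the thinning of counts (which first compared fold changes before and after, a ratio nearly fixed by construction at 0.958 and 0.922, and then the direction of the calls), the plant line as the whole of the effect and regroupings of its A6 libraries, the share of the most abundant genes, the stage of the A6 groups, reads shared between genes, and the differences of the MLA1 and isolate effects between times.

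Most genes called for MLA1 under K1 at 24 hpi were lower: 254 of 387. Lower depth of the avirulent libraries was argued against, since 10 thinnings of the 6 libraries to 67605 counts gave 121 to 155 calls with a median of 75.4% lower (73.5% to 81.6%), and so was a scaling shift by a few abundant genes. The 50 most abundant took 12.6% to 13.4% of the counts with MLA1 and 11.9% to 12.0% without it, a shift of -0.0157 in all other genes (log2, -0.0246 to -0.0102 over pairs of libraries), while the smallest fall called was 0.379. DESeq2 gave 195 lower of 349. The plant line as the whole of the effect, whatever the isolate, was not decided. Under A6 the same 387 genes moved by 0.183 of their change under K1 (resampled 95% range 0.136 to 0.212), below a bound of 0.5 set afterwards. The genes were chosen by their change under K1 in the same libraries, which enlarges that change and lowers the ratio. Tested directly, the MLA1 effect at 24 hpi differed between isolates in 50 genes, or 2 without avirulent replicate 2. The resampled range crossed the bound of 0.2 set beforehand. As 294 of the 387 went the same way under A6, a part shared by both isolates may remain. That range resamples genes and not libraries: of the 9 other ways to split the 6 A6 libraries 1 gave a larger ratio in size, 0.213, so such a part cannot be told apart from none. A response of K1 to recognition by MLA1 is a hypothesis found and tested on the same data. The number of its calls rests much on avirulent replicate 2, without which 54 genes were higher and 115 lower (76 and 208 or 85 and 192 without replicate 2 or 3 of K1 lacking MLA1). That replicate was the deepest of its group, at 216597 counts against 67605 and 132159, so its omission also removed depth. The loss of calls therefore does not show whether this library carried the effect.

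Most genes called between avirulent and virulent libraries at 6 hpi were higher: 77 of 97. An isolate difference without MLA1 could account for part, as these genes differed between K1 and A6 on plants lacking MLA1 at the later times by 0.318 of the avirulent fold, between the bounds of 0.1 and 0.5 set beforehand. Recognition by MLA1 at 6 hpi stayed open only as a part. With K1 on both plants these genes moved by 0.358 of the avirulent fold (median 0.287 against 0.801 in log2, quartiles 0.179 and 0.395). This ratio reuses the avirulent libraries in which the genes were chosen, which enlarges it. It argues against recognition as the whole of the difference in these 97 genes. The direct contrast called 0 genes (edgeR, 289 at an unadjusted p < 0.05, DESeq2 0). Greater depth of the avirulent libraries could not be tested, since thinning to 238766 counts left 2 to 20 calls (median 66.7% higher, 50% to 100%). How much the isolate difference, recognition and depth each contributed cannot be told. Without avirulent replicate 1, 2 or 3 the 97 genes became 25, 0 and 11. Without replicate 1, 2 or 3 of K1 on plants lacking MLA1 they became 189, 203 and 251.

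All 11 genes called in the interaction of plant and isolate at 18 hpi were higher. An earlier stage of the whole fungal programme in 1 of the 2 K1 groups was looked for in genes that rise after 18 hpi. These were the other 77 genes that rose at least 2-fold from 18 to 24 hpi in A6. They moved by -0.0692 of the called genes' effect of MLA1 under K1. In the A6 groups they moved by 0.0683 of the called genes' effect of MLA1 (median falls of 0.0391 and 0.573 in log2). That argued against a shift of stage only for genes rising after 18 hpi. Genes rising from 12 to 18 hpi, as bghG000359000001001 and bgh06754 did in virulent infections, were not looked at. A group lagging before 18 hpi therefore stays open. The same reads counted under all 11 identifiers were argued against by the correlation of deviations from group means, 0.253 at the median of 55 pairs over libraries. Reads of 1 transcript divided among identifiers need not raise this correlation, so that stays open. Low counts also limit it, as for bghG000359000001001 with 11 counts over the 9 virulent libraries at 12 hpi. In 1 pair, bghG000349000003001 and bghG000347000001001, the correlation was over 0.9 (0.945), so reads shared between some of the genes stay open. On plants lacking MLA1 the median difference between K1 and A6 for these genes was 1.86 at 6 hpi, 1.27 at 12 hpi, -1.98 at 18 hpi and 0.19 at 24 hpi (log2), where the value at 18 hpi reuses libraries in which the genes were chosen. A difference in timing between isolates that is alike on both plants cancels in the interaction. These values therefore do not bear on why its calls were all higher. The count became 0 without replicate 3 of A6 or 2 or 3 of K1 on plants with MLA1, or without replicate 3 of A6 or 1 or 2 of K1 on plants lacking it, 1 without replicate 1 of A6 with MLA1, and 17 without replicate 2 of that group.

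Differences between groups were tested in several further contrasts. The step from 18 to 24 hpi differed between avirulent and virulent infections in 27 genes (6 higher, 21 lower), and the effect of MLA1 at 24 hpi differed between isolates in 50 (3 higher, 47 lower). Under K1 the MLA1 effect at 24 hpi differed from that at 6 hpi in 50 genes (12 higher, 38 lower), at 12 hpi in 71 (18 and 53) and at 18 hpi in 38 (7 and 31). DESeq2 gave 98 (48 and 50), 103 (40 and 63) and 89 (37 and 52). Without replicate 2 of K1 on plants with MLA1 at 24 hpi these became 16, 17 and 15. The 50 became 33 without replicate 2 or 3 of K1 with MLA1 at 6 hpi and 24 without replicate 3 of K1 lacking it. The 71 became 43 without replicate 1 of K1 with MLA1 at 12 hpi, 37 without replicate 2 of K1 lacking it at 12 hpi and 46 without its replicate 3 at 24 hpi. The 38 became 20 without replicate 2 of K1 with MLA1 at 18 hpi and 21 without replicate 1 at 18 hpi or 3 at 24 hpi of K1 lacking it.

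The isolate difference on plants lacking MLA1 changed between 6 and 12 hpi in 91 genes (25 higher, 66 lower), between 12 and 18 hpi in 313 (200 and 113, or 168 and 154 with library totals alone) and between 18 and 24 hpi in 63 (37 and 26). The 91 became 56 without replicate 3 of A6 at 6 hpi and 58 without replicate 3 of K1 at 12 hpi.

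Values of the 9 virulent libraries of a time, library totals or log2 CPM of named genes, were checked in 44 groups. In 3, all of named genes, a library was set apart by more than the 95% critical value of Dixon's ratio, 0.493. Chance flags about 1 in 20 where the 9 libraries are alike, but each group pools 3 combinations of plant and isolate. In log2 CPM, replicate 2 of A6 lacking MLA1 at 6 hpi was at 4.33 for bgh02329 (others 2.79 to 3.49, ratio 0.542). Replicate 1 of K1 lacking MLA1 at 12 hpi was at 7.37 for bghG004376000001001 (others 6.38 to 6.81, ratio 0.563), and replicate 3 of that combination at 18 hpi was at 8.70 for bghG005335000001001 (others 7.46 to 8.08, ratio 0.502).

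Regroupings of the same libraries into groups of the same sizes, 100 where more were possible, gave the following. For avirulent against virulent, 2, 4, 2 and 1 of 100 gave as many genes at 6, 12, 18 and 24 hpi, the real one included (real 97, 9, 43 and 340, highest other 125, 25, 43 and 84), a share under 1 in 20. These regroupings put single libraries together at random. They break up the 4 combinations of plant and isolate and do not test 1 combination against the others. The share was under 1 in 20 for the virulent steps as well, with 1 of 100 each (3876, 2548 and 1096 against 2169, 1237 and 594). It was 3 for the step difference from 18 to 24 hpi (27 against 68) and 2 for the interaction at 18 hpi (11 against 13). The isolates over the mean of times (811 against 300) and their change from 12 to 18 hpi (313 against 287) had 1 each. None of these shares was adjusted for the number of comparisons, so those of 2, 3 or 4 of 100 leave chance open. The regroupings gave no verdict for the step differences from 6 to 12 and 12 to 18 hpi or the interaction at 6 and 12 hpi, since any count is as large as 0: each had 0 genes in edgeR (388, 391, 294 and 256 at an unadjusted p < 0.05, DESeq2 4, 1, 0 and 0), 100 of 100 as large and highest others of 255, 34, 10 and 2. Chance was not excluded for the MLA1 effect under A6 over the mean of times with 7 (1 against 2). The share was also over 1 in 20 for the interaction at 24 hpi with 11 of 100 (50 against 339), the MLA1 effect under K1 at 24 hpi against 6, 12 and 18 hpi with 13, 11 and 10 (50, 71 and 38 against 205, 210 and 434), and the isolate difference between 6 and 12 hpi with 9 (91 against 379) and between 18 and 24 hpi with 14 (63 against 332), but there the others as large left part of the real grouping in place, so these shares do not decide on chance.

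Regroupings that called several times the real number point to a structure of the samples. For the interaction at 24 hpi, all 10 other regroupings with as many genes left 1 of the contrast's parts as it was, and the highest of those leaving neither part gave 3. In the same way the highest leaving neither part gave 1, 2 and 4 for the MLA1 effect under K1 at 24 hpi against 6, 12 and 18 hpi, and 2 and 5 for the isolate difference between 6 and 12 and between 18 and 24 hpi. The step difference from 6 to 12 hpi reached 255 with no part left as it was.

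With 3 libraries against 3 there are 10 regroupings, too few for a share under 0.05. The real counts and highest others were 2698 and 0, 1203 and 1, and 417 and 1 for the avirulent steps (1 of 10 as large in each). For MLA1 under K1 they were 0 and 1, 0 and 0, 33 and 1, and 387 and 3 at 6, 12, 18 and 24 hpi (10, 10, 1 and 1 as large; edgeR 289 and 273 at an unadjusted p < 0.05 and DESeq2 0 at the first of these times and at 12 hpi). For MLA1 under A6 they were 2 and 2, 0 and 0, 1 and 2, and 1 and 0 (2, 10, 2 and 1 as large; 205 unadjusted and DESeq2 0 at 12 hpi). For K1 against A6 lacking MLA1 they were 453 and 1, 409 and 6, 487 and 3, and 156 and 1 (1 as large in each).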

How the results depend on the processing

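Library totals alone, omission of the 2 libraries under 100000 counts and rows with identical counts taken once were added after the data were seen. Counts of genes in the main comparisons, both directions together, stayed within 1.5 times under RLE factors (24 results), library totals alone (24), the stricter filter (24), identical rows taken once (23) and the 36 virulent libraries alone (4). Their split into higher and lower did not always do so, as given above for steps into and out of 12 hpi with library totals alone. The counts moved under the following settings, and the cause was not tested. With 16 groups, avirulent against virulent gave 430, 310, 336 and 578 genes at 6, 12, 18 and 24 hpi, in place of 97, 9, 43 and 340. With the 12 libraries of 1 time it gave 0 at 6 hpi (edgeR, 781 unadjusted in the fit of 48, DESeq2 116) and 3 at 12 hpi. Without the filter it gave 5 at 12 hpi, and the interaction at 18 hpi 7 in place of 11. DESeq2 gave 33 at 12 hpi and 69 at 18 hpi, step differences of 4, 1 and 53 in place of 0, 0 and 27, 76 for MLA1 under K1 at 18 hpi in place of 33 (92 with the 6 libraries alone), and 0 for MLA1 under A6 over the mean of times in place of 1, as did omission of libraries under 100000 counts (edgeR 342 unadjusted). The replicate block gave 1 for the interaction at 6 hpi in place of 0. For MLA1 under A6 at single times, it gave 1 at 6 hpi in place of 2 and 2 at 18 hpi in place of 1, no filter 5 and DESeq2 1 at 6 hpi, and omission of libraries under 100000 counts 2 at 18 hpi and 0 at 24 hpi in place of 1 each (edgeR 306 unadjusted, DESeq2 1). Deviations of libraries sharing a number correlated between -0.0752 and 0.0848, so the numbers pair no libraries.

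With each library left out in turn, avirulent against virulent ranged from 0 (avirulent replicate 2) to 251 (K1 lacking MLA1 replicate 3) at 6 hpi, 0 (avirulent replicate 1) to 108 (K1 lacking MLA1 replicate 2) at 12 hpi, 2 (avirulent replicate 1) to 93 (K1 lacking MLA1 replicate 1) at 18 hpi and 123 (avirulent replicate 2) to 358 at 24 hpi. Step differences ranged from 0 to 5, 0 to 1 and 3 to 31, the avirulent step from 18 to 24 hpi from 216 to 358, MLA1 under K1 from 1 to 34 at 18 hpi and 169 to 348 at 24 hpi, MLA1 under A6 over the mean of times from 0 to 5, and the interaction from 0 to 19 at 6 hpi, 0 to 17 at 18 hpi and 2 to 71 at 24 hpi. The lowest at 24 hpi were each without avirulent replicate 2, the deepest library of its group. Ratios of totals crossed 1 at 12 hpi against virulent libraries (0.792 to 1.08), A6 with MLA1 (0.707 to 1.15, and 1.03 without avirulent replicate 3) and K1 lacking MLA1 (0.879 to 1.44), and at 18 hpi against virulent libraries (0.961 to 1.27) and A6 with MLA1 (0.901 to 1.19, and 0.945 without A6 replicate 3). Named genes kept their direction in these omissions, with the call kept in 580 and lost in 108. Over the other settings they lost it in 5 results without libraries under 100000 counts, 5 with the 12 libraries of 1 time, 4 without the filter, and 1 each with RLE factors, the block and DESeq2, which gave 17 of them no adjusted p. Under the stricter filter only 48 of the 58 results could be tested, and all of those kept their call.

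At 24 hpi simulated 1.5-fold changes were recovered in 31.2% for MLA1 under K1 (38.8% at 6 hpi) and 4.62% for the interaction. For avirulent against virulent the share was 21.2%, which may be too high, as the simulated spread came from the fit of 16 groups. No simulation varied depth alone. Lists of gene groups with both kinds of camera correlation and with RLE factors, effector peak times, scaling without candidate effectors and peak times of all candidate effectors were not run, as no identifier carried a name.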

Other observations

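The classes of genes by time of highest level, the identifier series and the isolate timing below were chosen after the data were seen. Genes with at least a 2-fold range over time in A6 were sorted by the time of their highest mean from the A6 libraries alone. These enter the contrast of MLA1 under K1 only through the filter, scaling and spread of the shared fit. Of the 455 genes highest at 24 hpi in A6, 80 (17.6%) were lower with MLA1 under K1 at 24 hpi, against 3.44% of all other genes (Fisher's exact test, odds ratio 5.98, adjusted p = 2.21e-27), and 26 (5.71%) were higher, against 2.12% (odds ratio 2.80). Of the 947 highest at 12 hpi, 101 (10.7%) were lower against 3.36% (odds ratio 3.44, adjusted p = 1.04e-17) and 38 (4.01%) were higher against 2.08% (odds ratio 1.96, adjusted p = 0.00159). Of the 230 highest at 18 hpi, 14 (6.09%) were higher against 2.26% (odds ratio 2.81, adjusted p = 0.00161) and 17 (7.39%) lower against 4.49% (odds ratio 1.70, adjusted p = 0.0591). Of the 824 highest at 6 hpi, 5 (0.607%) were lower against 5.32% (odds ratio 0.109, adjusted p = 4.73e-12) and 13 (1.58%) higher against 2.56% (odds ratio 0.610, adjusted p = 0.108). Fisher's test takes genes as independent, which they are not. The classes were also not matched for abundance at 24 hpi, which affects the chance of a call in either direction. Camera was run in the K1 libraries alone, on the 813, 933, 222 and 435 genes of the 6, 12, 18 and 24 hpi classes that passed the filter there. With a preset correlation no class passed at any time; the smallest adjusted p was 0.0673, for the 24 hpi class at 24 hpi and others. With an estimated correlation the 12 hpi class was lower at 18 hpi (adjusted p = 0.0350), while at 24 hpi the 12 hpi class had adjusted p = 0.0613 and the 24 hpi class 0.126.

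The course of expression was much alike in the isolates on single genes: of the 2403 genes with a class in A6 that passed the filter in the K1 libraries, 2003 (83.4%) had their highest mean at the same time in K1 on plants lacking MLA1, against 30.2% if the times were independent. The share was 92.5% for genes highest at 6 hpi, 87.4% at 12 hpi, 47.3% at 18 hpi and 76.1% at 24 hpi. In the 200 genes whose isolate difference rose from 12 to 18 hpi and the 113 in which it fell, the differences at those times are set by the choice of genes. In the libraries not used for it, the median differences (K1 minus A6, log2) were -0.0407 and 0.256 at 6 hpi, with 29 higher and 16 lower calls and 33 and 7, and 0.122 and -0.0106 at 24 hpi, with 9 and 1 and 5 and 7.

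The table held 2 series of identifiers, bghG with 887 and bgh with 5590. Of the 583 bghG genes in the fit of the A6 libraries, 207 (35.5%) were in the 12 hpi class, against 740 of 4623 (16.01%) in the other series, an odds ratio of 2.89 (Fisher's exact test, p = 2.20e-26). What the series stand for is not given in the sources used here.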
